A study of Homo sapiens with 4 samples.

How the data were processed

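One pool of cells from 10 tumours was measured by droplet single-cell sequencing of the 3' ends of transcripts (10x Genomics Chromium). OVCAR5 is an established human ovarian carcinoma line. The line used here carried a reporter that senses interferon gamma (IFN-γ) and the cyan fluorescent protein CFP, and it had been grown as tumours in NSG mice lacking mouse B2m, per the labels. The labels name 4 conditions: tumours exposed or not exposed to T cells, taken 16 or 44 h later, with 3 exposed and 2 unexposed tumours at each time. The cells of each tumour were stained with hashtag antibodies, which carry a DNA tag that marks the tumour of origin, and were then combined. CFP-positive cells, which the labels call bystander cells, were sorted from the combined suspension, while the sample titles speak of CFP and GFP cells. The 4 samples of the series were 2 gene expression libraries and 2 hashtag libraries of this one pool, sequenced in 2 runs.

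The deposited matrix holds raw UMI counts, that is, counts of distinct molecules per gene and cell barcode, with no normalization, per the file headers and the values. It held 36602 gene features, among them a custom feature named Katushka (a far-red fluorescent protein), and 10 hashtag features, over 6926 deposited barcodes. The matrix header names Cell Ranger 5.0.1, whereas the submitters' processing notes name Cell Ranger 2.1.1 and the genome build GRCh38. The annotation release and how the barcodes were chosen are not given in the sources used here. Both runs were merged in the matrix, so no value could be compared between runs. Reads of mouse host cells that match the human genome would be counted as human.

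The hashtags in the file carry numbers only, and no label ties a number to a condition. Therefore the planned comparisons of exposed with unexposed tumours at 16 h, at 44 h, over both times and between times, and the gene list tests between those groups, were not made. Condition was not read from hashtag order or from expression. Tumours are named by hashtag number (tumour 1 to tumour 10), and each tumour's value or the range and median over tumours is given. The 10 tumours mix the 4 conditions, so a relation across tumours can arise from condition.

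Barcodes were assigned to hashtags with HTODemux of Seurat 5.3.0 (positive quantile 0.99), which called 5262 barcodes with 1 hashtag, 1558 with several (treated as doublets and removed) and 106 with none. Of the 1558, 1337 had at least 60% of their hashtag counts on 1 hashtag, and 423 of these had hashtag 6 on top. Cells needed at least 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs. This left 2134 cells, and 3925 barcodes (56.7%) lay over the mitochondrial limit. No second doublet caller was run. For shares of cells, phase calls, list scores and correlations across cells, each cell was thinned at random to 5000 UMIs, which left out 131 of the 2134 cells. Shares of cells within clusters, and of barcodes with no hashtag call, were taken from unthinned counts instead. Intervals on shares are exact (Clopper-Pearson) at 95% and cover counting error only. Where a share was 0, the upper end of this interval is given, and where a CPM was 0, the CPM of 3 counts.

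Counts were summed per tumour and normalised with the TMM method of edgeR 4.0.16. A list value is the mean over members of log2 CPM (prior count 2), using members with at least 10 counts in all. The spread of a gene over tumours was its edgeR biological coefficient of variation in an intercept-only fit, over genes with a mean of at least 10 CPM, and genes differing at least 4-fold between the highest and the lowest tumour were counted, with a floor of 3 counts per tumour. The first filter run for this spread was edgeR's filterByExpr, and it was replaced by the mean of 10 CPM after it was seen to leave out CXCL10. Correlations of list values over the 10 tumours used Pearson's r and Spearman's rho with two-sided permutation tests (100000 resamples), Benjamini-Hochberg adjustment over the pairs tested, and a repeat without the 2 tumours farthest from the median. Lists whose tumours passed a limit for division into separate parts were not pooled. The rule for this was a silhouette of 0.7 or more for the best division into 2 parts. It was set after the list values had been seen and was run first. A limit simulated from 5000 sets of 10 normal draws (their 95th percentile) was run next, 0.7 was then taken up again with both results known, and a limit of 0.65 was run last. The IFN-γ list lay just under 0.7, so its correlations over the 10 tumours hinge on this choice, and they are also given within the 6 tumours of the lower part.

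Within each tumour, Spearman's rho between list scores (mean log-normalised value of the members after thinning) was computed over cells. The 10 values per pair were tested against 0 by an exact two-sided sign-flip permutation test with 1024 flips, whose smallest possible p is 0.00195, and adjusted over 66 pairs. Medians of pairs with the IFN-γ or the TNF-NF-κB list were also set beside 1000 random gene lists of the same size, matched on mean expression. The other pairs were not. Single genes with a UMI in at least 5% of cells (8369 genes) were correlated with the IFN-γ list in the same way.

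Cells were called cycling (S or G2-M) or non-cycling from the S phase and G2-M phase lists after thinning, with scanpy's cell cycle score. Counts were summed per tumour and class, the members of both lists were left out, and the classes were compared with edgeR's quasi-likelihood F test with tumour as a block. Gene lists were tested on the same fit with camera (limma 3.58.1; preset correlation and estimated correlation) and with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. The block came from the design itself, since both classes were taken from each tumour. P-values of this comparison set the difference between the classes against its variation over these 10 tumours. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 components, 15 neighbours, resolution 0.5). A cluster was to be named only from fixed markers, and defining genes of clusters are given as descriptions. Positions of genes are from GENCODE 29 on GRCh38 and were used as annotation only.

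Before the data were examined, 12 gene lists (IFN-γ response, MHC class I and class II presentation, type I interferon-stimulated genes, TNF-NF-κB response, S phase, G2-M phase, p53 and apoptosis, hypoxia, unfolded protein and amino acid stress, immediate early and heat shock genes that dissociation can induce, and TGF-β and mesenchymal genes), 6 marker lists (OVCAR5 epithelial cell, T cell, myeloid cell, fibroblast, endothelial cell and erythroid cell), the tests and the rule for named genes were fixed. The rule took the 3 members of each list with the highest mean CPM, 18 genes set in advance, the 15 genes outside the interferon and MHC lists most positively and the 10 most negatively correlated with the IFN-γ list, the 10 genes with the largest spread over tumours, the 5 leading genes of each cluster, and, for the comparison of cycling with non-cycling cells, the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, at least 10 CPM in the higher class and no overlap of the classes over tumours. Further genes were named after their values had been seen: list members other than the 3 most abundant, markers of other cell types, Katushka, and genes that set apart the cluster led by KRT81. Some genes that the rule names are not reported here. Thresholds of 4-fold and of 0.5 for the coefficient of variation, the depth of 5000 UMIs, the minimum of 10 counts for a list member, and the limit of 5 UMIs for a cell high in CXCL10 were also set after the files had been looked at.

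Each step that computed a statistic over many genes was tested on simulated data. For the spread over tumours, 90.5% of 200 genes made variable were recovered among the top genes. For genes correlated with the IFN-γ list, 98.5% of 200 planted genes were recovered. For cycling against non-cycling cells, 93% of genes changed 2-fold and 59% of genes changed by 0.5 on the log2 scale were recovered. Of 155 calls, 3 were unchanged genes. That simulation changed 200 of 8739 genes, equally up and down, whereas 4768 were called in the data. It therefore does not measure the error of a comparison in which so many genes differ. Alternatives covered DESeq2 1.42.0 size factors and its Wald test, another hashtag rule (top hashtag with at least 10 counts and at least 60% of a cell's hashtag counts), no filter on cells, a stricter filter, doublets kept, unthinned counts, rank and z-scored list scores, non-cycling cells alone, no filter on low counts, other cluster settings and each tumour left out. Chosen after seeing the data were a limit of 40% mitochondrial UMIs, leaving out the clusters led by KRT81 and COL3A1, the fit without the tumour block, leaving out each tumour in the cycling comparison, the other silhouette limits and a correlation over 6 tumours alone. Depth per tumour ran from 1082756 to 4349638 UMIs in cells past the filter.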

Results

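OVCAR5 ovarian carcinoma cells from 10 mouse tumours were read in one pool, and 2134 cells past the filter were traced to a tumour by hashtag, from 96 cells in tumour 10 to 346 in tumour 1. The median cell held 10601 UMIs and 3323.5 genes, with 15.1% mitochondrial UMIs. Which tumours had been exposed to T cells is not given by the labels, so the text below describes tumours one by one and cells within tumours.

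Genes that cells switch on in response to IFN-γ, the cytokine that activated T cells release, spanned more between tumours than any other pathway list except MHC class II. The IFN-γ response list ran from 3.18 mean log2 CPM in tumour 5 to 6.76 in tumour 7 (median 4.57), a span of 12.0-fold. The MHC class II list, whose products show peptides to CD4 T cells, spanned 4.47 on the log2 scale, from 2.33 in tumour 10 to 6.80 in tumour 8 (median 3.34). The MHC class I list, whose products show peptides to CD8 T cells, ran from 7.31 to 9.08 (span 1.77), and the type I interferon-stimulated list of antiviral genes from 5.42 to 7.53 (span 2.11). The TNF-NF-κB list of inflammatory genes ran from 3.69 in tumour 10 to 5.19 in tumour 8 (span 1.49).

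**Figure D1:**
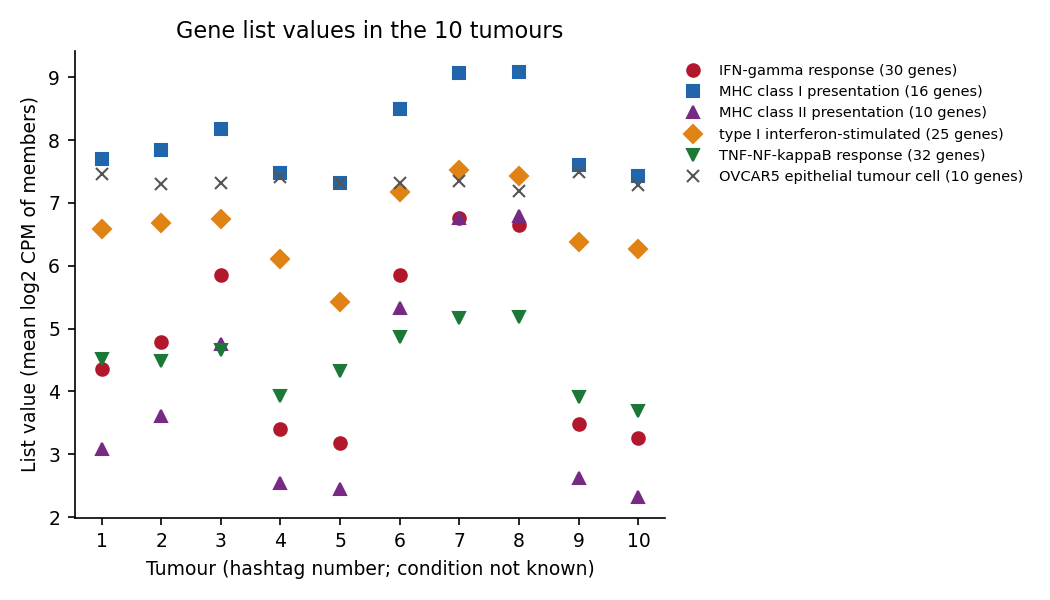
Mean log2 CPM of the members of 6 gene lists (vertical axis) in each of the 10 tumours, in order of hashtag number (horizontal axis). Each point is 1 list in 1 tumour, with symbols and colours for lists; the IFN-γ response list spanned 3.58 on the log2 scale.

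Single genes spanned far more than their lists. CXCL10, a chemokine that draws T cells, ran from 0.869 CPM in tumour 10 to 1274 CPM in tumour 8 (median 119), 460-fold over the detection floor. IDO1, an enzyme that breaks down tryptophan, ran from 0.886 to 1117 CPM, with its highest level in tumour 7, and CXCL11, a ligand of the same receptor as CXCL10, from 0.443 to 398 CPM. CXCL9, the third ligand of that receptor, ran from 0 in tumours 9 and 10 (3 counts would be 2.06 and 2.77 CPM) to 57.5 CPM, and CD274, which encodes the checkpoint ligand PD-L1, from 0.886 to 39.9 CPM. The guanylate-binding protein genes GBP1 and GBP4 spanned 34.7-fold and 39.1-fold. IRF1, a transcription factor of the pathway, spanned 12.1-fold. PLAAT4 reached 1500.3 CPM from 285 CPM.

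Among antigen presentation genes, HLA-DRA spanned 44.0-fold and CD74, the class II invariant chain, 23.5-fold, up to 1312 CPM. B2M, the light chain of MHC class I, was abundant in every tumour (4322 to 11374 CPM, 2.63-fold), as was HLA-B (3.27-fold). Of the most abundant type I interferon-stimulated genes, ISG15 spanned 3.85-fold, IFI6 3.13-fold and IFI27 1.97-fold. In the TNF-NF-κB list, the adhesion molecule gene ICAM1 spanned 5.06-fold, TNFAIP3, an inhibitor of NF-κB, 7.61-fold, the neutrophil chemokine genes CXCL1 and CXCL8 4.31-fold and 3.94-fold, BIRC3, a survival gene, 3.19-fold and NFKBIA, the inhibitor of NF-κB, 2.72-fold. The abundant members LCN2 and IER3 spanned only 1.90-fold and 1.44-fold.

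Of 8633 genes at a mean of at least 10 CPM, 190 differed at least 4-fold between the highest and the lowest tumour, and 53 of the 190 belonged to the interferon and MHC lists, which had 74 members at that level. These were 23 of 25 IFN-γ members, 8 of 8 MHC class II members, 6 of 16 MHC class I members and 16 of 25 type I members. The 10 genes with the largest spread were CXCL10, IDO1, CXCL11, GBP5, CXCL9, HLA-DPB1, MSMP, HLA-DQB1, HLA-DPA1 and HLA-DRA, of which only MSMP, encoding a secreted protein first found in prostate tissue, lies outside those lists. The cells of cluster 7, led by KRT81 and S100A9, held 2099 of the 2167 MSMP UMIs, and tumour 8, where MSMP was highest, had 3 cells of that cluster. The median coefficient of variation between tumours was 0.0983, and 66 genes exceeded 0.5. With no filter on cells 124 genes differed 4-fold, 114 of them shared with the 190. A limit of 40% mitochondrial UMIs gave 130, leaving out tumour 10 gave 153, and leaving out each other tumour 161 to 192. Interferon and MHC list members among them were 51, 53 and 52 in the first 3 settings, but 40 without tumour 5. The 4-fold count has no error term, so counting error can add genes to it.

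The other pathway lists spanned less than these 5. The S phase list of DNA replication genes (NASP, TYMS and PCNA its most abundant) spanned 0.45 on the log2 scale and the G2-M list of mitosis genes (TUBB4B, CKS1B, TOP2A) 1.11, with MKI67, a marker of dividing cells, at 28.7 to 90.4 CPM. Of 41 G2-M members at 10 CPM or more, 7 differed at least 4-fold between tumours, among them TOP2A (4.88-fold), which untangles DNA. Of 31 S phase members, 0 did. TOP2A and MKI67 were lowest in tumour 10, which had the fewest cells (96). At equal depth 5 of its 87 cells were called G2-M and 23.0% cycling, so its low G2-M values rest on few cells. The p53 and apoptosis list spanned 0.58, and its abundant members PMAIP1, CASP4 and XAF1 spanned 1.70-fold, 2.51-fold and 4.87-fold. Hypoxia genes spanned 0.71, up to 5.34 in tumour 5 against 5.07 in the next highest, tumour 8. The glycolysis genes LDHA, ENO1 and PGK1 spanned 1.47-fold, 1.33-fold and 1.33-fold. The unfolded protein and amino acid stress list spanned 0.37, with the chaperone genes HSP90B1, CALR and HSPA5 at 1.36-fold, 1.44-fold and 1.37-fold. Immediate early and heat shock genes, which tissue dissociation can induce, spanned 0.59 (FOS 1.72-fold, DUSP1 1.77-fold, HSPB1 1.60-fold). TGF-β and mesenchymal genes spanned 0.47 (VIM 1.30-fold, FN1 2.22-fold, TGFBI 1.77-fold).

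Markers of epithelial cells were even across tumours, with the OVCAR5 epithelial list at 7.19 to 7.49 and the keratin gene KRT8 spanning 1.21-fold. Markers of other cell types were scarce: the T cell list, with 5 members measured, lay at 1.11 to 2.35, and the myeloid list at 1.17 to 2.51. The fibroblast list, with 4 members measured, had a median of 0.55 and reached 3.48 in tumour 3, 2.82 in tumour 9 and 2.76 in tumour 5. Cluster 9, with 3 cells in each of these tumours, held 93 of the 96 UMIs of the fibroblast marker COL3A1. In unthinned counts only 7 of the 2134 cells held COL3A1, so its differences between tumours rest on few cells. The single endothelial marker measured lay at 1.77 to 3.44, and no erythroid marker had enough counts for a value. After thinning to equal depth, 0 of 2003 cells held a UMI of CD3D, CD3E, GZMB, CSF1R or HBB (upper limit 0.184%), while LYZ, a leading gene of cluster 6, was seen in 5.24%, COL1A1 in 1.90%, TYROBP in 1.45% and CD8A in 0.200% (4 cells).

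CXCL10 and IDO1 transcripts were concentrated in part of the cells. At equal depth, 14.5% of cells (95% interval 13.0 to 16.1%) held a CXCL10 UMI and 18.4% (16.7 to 20.2%) an IDO1 UMI. GBP1 was seen in 34.5% of cells and IRF1 in 51.4%, while B2M was seen in 99.95%. CD74 was seen in 37.0% of cells, ICAM1 in 24.4%, HLA-DRA in 16.9%, TNFAIP3 in 8.59% and CD274 in 5.94%. Intervals cover counting error only, and unthinned counts gave 10.2% for CD274, 39.9% for ICAM1 and 14.9% for TNFAIP3.

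The share of cells with CXCL10 was highest in tumour 7 (49.7%, interval 41.9 to 57.5%) and tumour 8 (36.9%, 30.8 to 43.4%), followed by tumour 6 (18.9%), tumour 3 (18.6%), tumour 2 (9.38%) and tumour 1 (4.83%). In tumours 4, 5 and 9 it was 0.939%, 2.76% and 0.820%, with no cell above 1 UMI, and in tumour 10 no cell held one (upper limit 4.15%). Single cells of tumour 3 and tumour 8 held up to 106 and 101 CXCL10 UMIs, and the 10% of cells with the most held 93.2% of all CXCL10 UMIs in tumour 3, 91.6% in tumour 6, 67.8% in tumour 8 and 58.1% in tumour 7. Evenly spread CXCL10 UMIs would have reached 96.7% of cells in tumour 3 and 99.9% in tumour 7. GBP1 was more widely seen, from 11.3% in tumour 4 to 74.9% in tumour 7. IDO1 ran from 0.469% of 213 cells in tumour 4 to 57.5% in tumour 7, and CD274 from 0.552% in tumour 5 to 17.4% in tumour 8. By CPM, IDO1 was lowest in tumour 5.

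**Figure D2:**
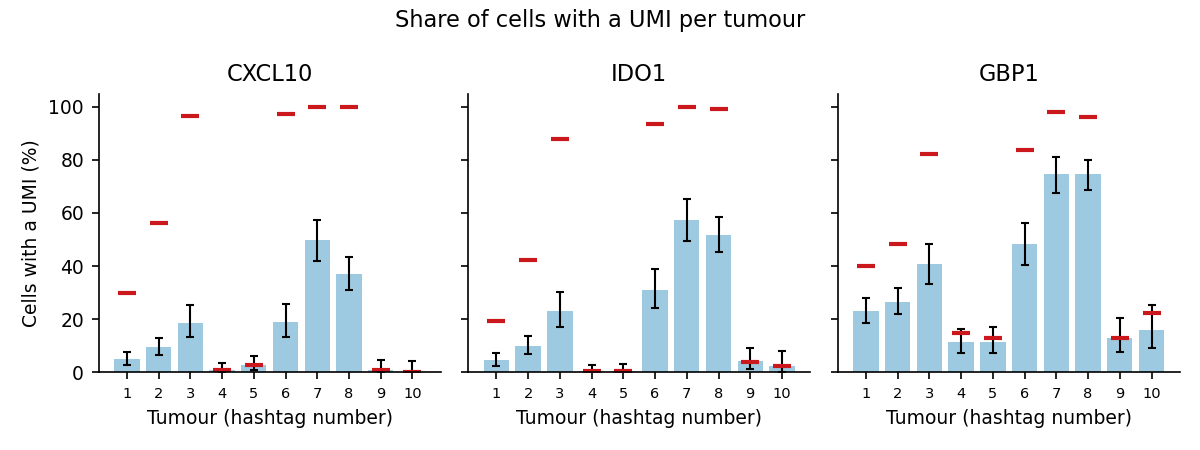
Percent of cells with at least 1 UMI of CXCL10, IDO1 and GBP1 after thinning to 5000 UMIs (vertical axis), for each tumour by hashtag number (horizontal axis). Bars are shares, black lines exact 95% binomial intervals and red marks the shares that evenly (Poisson) spread UMIs would give; for CXCL10 the bars ran from 0 in tumour 10 to 49.7% in tumour 7.

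Across tumours, MHC class I, type I interferon-stimulated, TNF-NF-κB, and p53 and apoptosis genes were high where IFN-γ response genes were high. In the p53 list the members with the highest r were XAF1 (r = 0.968), which is also in the type I list, CASP1 (r = 0.965), an inflammatory caspase gene, and the death receptor gene FAS (r = 0.940). Members of that list went different ways: r was 0.750 for TNFRSF10B, 0.736 for PMAIP1 and 0.610 for BBC3, but 0.316 for MDM2, -0.014 for BAX, -0.185 for CDKN1A and -0.659 for SESN1. In the TNF-NF-κB list, IL32, SOD2, ICAM1 and CCL2 had r of 0.987, 0.961, 0.957 and 0.957, against 0.451 for CXCL8, 0.472 for LCN2 and -0.636 for IER3.

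The MHC class II and immediate early lists were not pooled over the 10 tumours, since their silhouettes were over 0.7. Of 45 pairs of the other lists, 9 were called, all positive. The IFN-γ list correlated with MHC class I (r = 0.965, rho = 0.988; two-sided permutation p = 1e-05, the smallest possible; adjusted p = 0.00015; r = 0.959 without the 2 tumours farthest from the median, tumours 7 and 8). With the p53 list r was 0.958 and rho 0.903 (permutation p = 5e-05, adjusted p = 0.000563; r = 0.919 without those 2), and with the type I list r was 0.916 and rho 0.988 (permutation p = 1e-05, adjusted p = 0.00015; r = 0.831 without them). With the TNF-NF-κB list r was 0.932 and rho 0.891 (permutation p = 0.00011, adjusted p = 0.00099; r = 0.860 without them). The limit that decides which lists are pooled was set after the list values had been seen. A limit of 0.65 on the silhouette leaves the IFN-γ list out and calls 1 of 15 pairs. The simulated limit of 0.7545 leaves no list out and calls 14 of 66 pairs. Under it MHC class II had r = 0.977 with the IFN-γ list (permutation p = 1e-05, adjusted p = 0.000132). Within the 6 tumours in the lower part of the IFN-γ list, MHC class I kept its call (r = 0.934, exact p = 0.00139, adjusted p = 0.0153) and MHC class II was called (r = 0.983, exact p = 0.00417, adjusted p = 0.0229), whereas the type I (r = 0.753, exact p = 0.0667), TNF-NF-κB (r = 0.729, exact p = 0.126) and p53 lists (r = 0.872, exact p = 0.0222, adjusted p = 0.0815) did not.

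Within tumours, cells with more IFN-γ response transcripts also held more MHC class I (median rho 0.640 over the 10 tumours, range 0.362 to 0.836) and type I interferon-stimulated transcripts (0.634, 0.448 to 0.736). They held more TNF-NF-κB (0.374, 0.105 to 0.741), MHC class II (0.353, 0.0987 to 0.729), and p53 and apoptosis transcripts (0.281, 0.111 to 0.391). They held fewer S phase (-0.193, -0.287 to -0.142) and G2-M transcripts (-0.227, -0.325 to -0.152). Each of these 7 relations had the same sign in 10 of 10 tumours and lay outside the central 95% of random lists matched on expression (exact permutation p = 0.00195, the smallest possible, two-sided; adjusted p = 0.00416). Hypoxia (-0.133) and immediate early genes (0.0942) passed the same test but lay inside the range of random lists, at percentiles 8.2 and 92.5. The unfolded protein (0.0118, exact p = 0.918) and TGF-β lists (0.0243, exact p = 0.248) were not called. Under the stricter cell filter, which left 266 cells, hypoxia lost its call (-0.107, exact p = 0.631) and TGF-β passed (0.301, exact p = 0.00781). That filter allowed at most 10% mitochondrial UMIs, and the median share was 9.26% in cluster 7 but 13.9% or more in each other cluster. It thus favours cells of cluster 7, and this was not separated from cell quality. Without the clusters led by KRT81 and COL3A1 the unfolded protein list had 0.0355 (exact p = 0.0449).

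**Figure D3:**
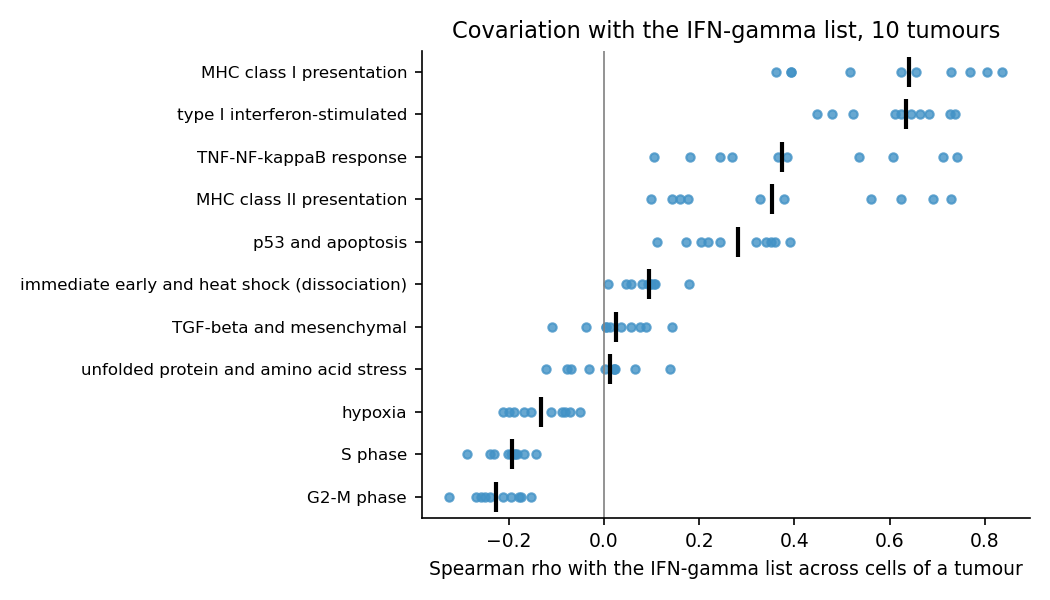
Spearman's rho across the cells of a tumour between the IFN-γ response list and another list (horizontal axis), for each other list (vertical axis). Points are single tumours and black ticks medians; the median rho was 0.640 for MHC class I and -0.227 for G2-M.

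Over all 66 list pairs, those with the IFN-γ list included, 44 were called within tumours, 24 positive and 20 negative. TNF-NF-κB genes followed MHC class I (median rho 0.386), MHC class II (0.281), type I (0.273), immediate early (0.25) and p53 genes (0.219) and ran against S phase (-0.164) and G2-M genes (-0.158). The pair of cell cycle lists had a median rho of 0.478. Only pairs with the IFN-γ or the TNF-NF-κB list were set beside random lists.

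Among single genes outside the interferon and MHC lists, 15 were named as the most positively correlated with the IFN-γ list from cell to cell. Being outside these fixed lists does not mean that a gene does not respond to interferon. IFITM3, which blocks virus entry, had a median rho of 0.444, TNFSF10, encoding the death ligand TRAIL, 0.419, and RNF213 0.415. EPSTI1 (0.378), ISG20 (0.376), an RNA-degrading enzyme, TNFSF13B (0.368), encoding the B cell factor BAFF, TXNIP (0.335), CFB (0.327), a complement gene, SAMD9L (0.324), TRIM22 (0.312) and SLFN5 (0.308) followed, along with LY6E, UBE2L6, TGM2 and SP100. The 10 most negative were the ribosomal protein genes RPS2 (-0.271), RPS7 (-0.252), RPLP0 (-0.245), RPL3 (-0.235) and RPL5 (-0.231), the histone gene H2AFZ (-0.252), NME2 (-0.229), RAN (-0.225) and the ubiquitin enzyme genes UBE2S (-0.224) and UBE2C. Each had the same sign in 10 of 10 tumours (exact permutation p = 0.00195, the smallest possible; adjusted p = 0.0306 over 8369 genes).

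In cycling cells, 18 of 19 IFN-γ response, 12 of 16 MHC class I, 4 of 4 MHC class II, 19 of 25 type I and 18 of 24 TNF-NF-κB members were lower than in the other cells of their tumour. With an estimated correlation camera called none of these 5 lists (adjusted p = 0.171 to 0.174). CXCL10 fell by 1.29 on the log2 scale (SE 0.18, adjusted p = 3.79e-07, lower in 8 of 10 tumours), IDO1 fell by 1.35 (SE 0.16, adjusted p = 1.86e-08) and GBP2 fell by 1.42. B2M fell by 0.52 (SE 0.04, adjusted p = 1.11e-12), CD74 fell by 0.93 and HLA-DRA fell by 1.23. Among type I genes ISG15 fell by 0.64 and IFITM1 fell by 1.23, and among NF-κB genes SOD2 fell by 1.00 and C3, the central complement gene, fell by 1.37. IRF1 fell by 0.73, while TAP1, the peptide transporter gene, had a value of -0.14 and IFI30 of -0.35 and neither passed.

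The largest rises outside the lists that defined the classes were in NCAPG (6.67, SE 0.21), a condensin subunit gene, CCNA2 (6.39), a cyclin gene, SPC25 (6.36), DEPDC1 (6.16), KIF14 (5.81), KIF15 (5.68), PIMREG (5.61), MCM10 (5.59), PLK1 (5.57), a mitotic kinase gene, and KIF20A. Among the largest falls were FAM214A (-2.40), KLHL24 (-2.24), BOC (-2.14), PNRC1 (-2.08), CCNG2 (-2.04), a cyclin gene linked to arrest, CREBRF (-2.04), SELENOP (-1.94), a selenium carrier gene, GABARAPL1 (-1.84), an autophagy gene, and FSIP2 (-1.78).

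Of 8739 genes tested with edgeR over 10 tumours, 2360 were higher and 2408 lower in the 482 cycling cells (24.1% of 2003; 18.6 to 30.2% per tumour). In the IFN-γ list 18 of 19 members fell and 0 rose (19 fell adjusted over the list alone); the camera adjusted p was 2.14e-07, and 0.171 with an estimated correlation. MHC class I had 12 of 16 lower (13 adjusted over the list alone; camera adjusted p = 6.11e-06, and adjusted p = 0.171 with an estimated correlation). MHC class II had 4 of 4 lower (4 adjusted over the list alone; camera adjusted p = 0.00259, and adjusted p = 0.174 with an estimated correlation). The type I list had 19 of 25 lower (20 adjusted over the list alone; camera adjusted p = 3.92e-07, and adjusted p = 0.174 with an estimated correlation). In the TNF-NF-κB list 18 of 24 fell (18 adjusted over the list alone; camera adjusted p = 0.000361, and adjusted p = 0.171 with an estimated correlation), and BIRC3 rose by 0.28.

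Immediate early and heat shock genes had 11 of 15 lower (12 adjusted over the list alone; camera adjusted p = 0.000746, and adjusted p = 0.171 with an estimated correlation), with EGR1 at -1.39 and FOS at -1.21, while the heat shock gene HSPH1 rose by 0.76. Of the p53 list 9 of 17 fell (9 adjusted over the list alone) and MDM2 and BAX rose, by 0.32 and 0.48; camera did not call it (adjusted p = 0.0510). Hypoxia (6 lower, 3 higher of 12; camera adjusted p = 0.728), unfolded protein (5 lower, 2 higher of 12; 0.126) and TGF-β genes (2 lower, 4 higher of 8; 0.797) were not called by camera. Within them the glycolysis genes SLC2A1, LDHA and ENO1 rose and VIM rose by 1.04, while FN1 fell by 1.60. In fry, which asks whether a list moves on balance one way, the IFN-γ, MHC class I, MHC class II, type I and TNF-NF-κB lists moved down (adjusted p = 0.000116, 2.14e-05, 0.000529, 0.000155 and 0.000116). So did the immediate early and heat shock (adjusted p = 2.36e-05), p53 (0.000418) and unfolded protein lists (0.00280), while hypoxia (0.463) and TGF-β (0.210) were not called. Classes were called from the same cells' transcripts, and cycling cells held more UMIs (median 15165 against 10044).

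**Figure D4:**
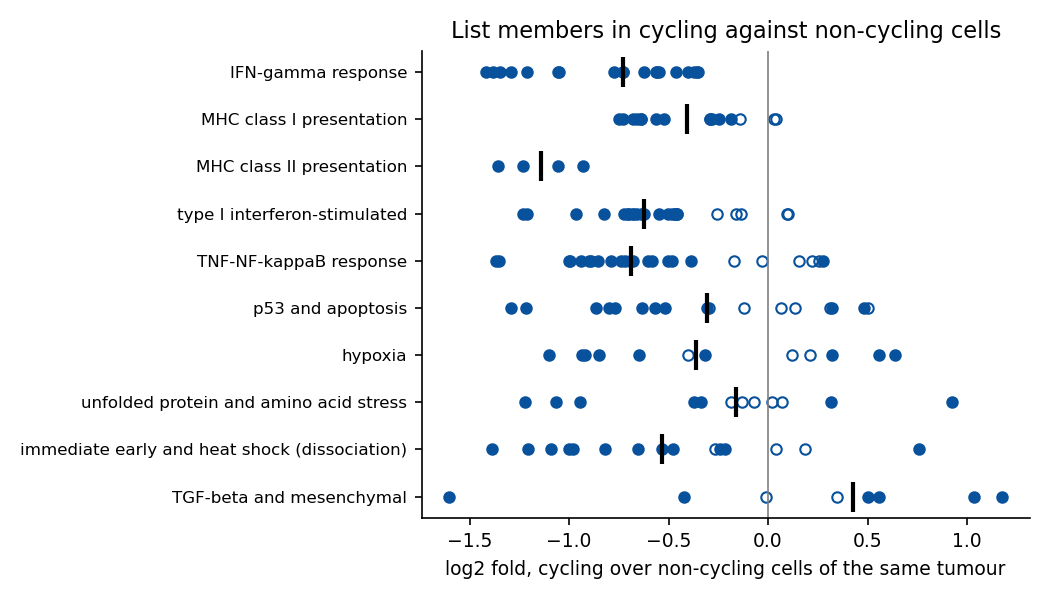
Log2 fold of cycling over non-cycling cells (horizontal axis) for the members of each gene list (vertical axis). Points are genes, filled where adjusted p was under 0.05, and black ticks are list medians; for CXCL10 the value was -1.29 and for B2M -0.52.

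Clustering gave 10 groups of cells, described by their leading genes. Shares of cells within clusters are from unthinned counts, so they also depend on depth. Cluster 1 (581 cells) was led by FABP4, PSCA, SHISA2 and CYP1B1, cluster 2 (429) by HP, SPOCK1, TSHZ2, NNMT and BDNF, and cluster 4 (301) by members of the G2-M and S phase lists, TOP2A, UBE2C, NUSAP1, HMMR and RRM2. Cluster 5 (173) was led by MT1E, PAEP, CALB2 and LINP1, cluster 6 by TSPAN8, TFF2, DMBT1, LYZ and GPX2, cluster 8 (69) by IGFBP5, CREB5, AKAP12, RHOQ and FILIP1L, and cluster 10 (28) by CEACAM6, ST14, CDH1, ACTL8 and MACC1. Cluster 9 (38) was led by COL3A1, APOE, COL1A2, COL1A1 and ZNF90, with KRT8 in 89.5% of its cells. COL3A1 and COL1A2 were seen in 13.2% of them and COL1A1 in 15.8%, while the myeloid markers TYROBP and AIF1 were seen in 68.4% and 57.9%.

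Cluster 3 (331 cells) was led by IDO1, CXCL10, CXCL11, HLA-DRA and HLA-DPA1, and 68.6% of its cells held CXCL10. It made up 48.9% of tumour 7, 46.3% of tumour 8, 22.2% of tumour 6, 21.7% of tumour 3, 7.76% of tumour 2, 4.62% of tumour 1 and 2.08% of tumour 10, and no cell of tumours 4, 5 and 9. Cluster 7 (79 cells) was led by KRT81, S100A9, MSMP, LDHB and DKK1 and was found in all 10 tumours. Other settings gave 8 to 13 clusters. Clusters 7 and 10 were found again with overlaps of at least 98.75%, but at resolution 0.25 the best overlap was 36.4% for cluster 2, 27.1% for cluster 5 and 35.2% for cluster 6, and at resolution 1 it was 47.3% for cluster 1, 43.8% for cluster 2 and 49.8% for cluster 4.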

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

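Collagen transcripts stood out in barcodes outside the report's comparisons: in 47 barcodes with no hashtag call that passed the quality filter, COL1A1 and COL3A1, the fibrillar collagens of connective tissue, reached 8880 and 7841 CPM, against 8.37 and 3.81 CPM in tagged cells. Of the tests in this part, the depth test and the swaps of the class labels were written after the results had been seen, and exploratory work had already shown the clusters and the collagen signal when the others were written. None of the 22 sets of tumour values compared held a tumour beyond the gap limit.

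The barcodes with no call held a median of 1774 UMIs, 868 genes, 0.418% mitochondrial UMIs and 37 hashtag counts, against 1966.5 hashtag counts in tagged cells. Free tumour RNA in empty droplets would bring the tumour's own keratin message, yet KRT8 stood at 9.46% of its level in tagged cells, which speaks against it. Cells other than OVCAR5 would lack keratins, and KRT8, KRT18 and KRT19 together stood at 10.6%. The myeloid list stood at 103 CPM against 58.0. This cannot decide on myeloid cells of the mouse, whose reads count only where they match the human genome. The fibroblast list stood at 23492 CPM against 15.7, so a fibroblast is a candidate. COL3A1 was seen in 74.5% of these barcodes, but DCN stood at 51.4 CPM, and the sort for CFP should have removed such cells. The line was grown in mice, so such a fibroblast could come from the mouse host, and a mouse origin was not tested.

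Cluster 7 expressed KRT81 at 2404 CPM against 1.83 in other cells and S100A9 at 2794 against 13.7, with a median of 21608 UMIs per cell. Pairs of cells from the other clusters read as 1 cell cannot exceed both parts. Yet 75.6% of the 667 raised genes of cluster 7 were more than 2 times as high as in any other cluster. This speaks against pairs drawn from the other clusters. The 667 had been picked as at least 4-fold higher, which favours this outcome, and the share ran from 0 to 87.3% in the other clusters. Pairs with a cell type that has no cluster of its own were not covered, and median depth was 2.04 times that of all cells. Cells of another origin would lack genes that all other cells share, and 11 such genes were at least 10-fold lower, among them IFI27, CYBA, S100A4 and CTNNA1 (2.39 against at least 160 CPM). No other cluster lacked a gene in this way, so cells of another human line are a candidate, while EPCAM at 509 CPM and the sort for CFP limit which. A comparison of genotypes would test this hypothesis and was not analysed here.

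CXCL10 UMIs were concentrated in part of the cells in 6 tumours. Cells of other tumours under a wrong hashtag were left open: cells high in CXCL10 differed in the share of their own hashtag by 0.646 percentage points (0.243 to 1.10 over 5 tumours), but all cells had been kept for 1 dominant hashtag, so this share could hardly fall. Depth would bring the share close to that of evenly spread counts, but it stayed at a median of -56.6 points from it over 6 tumours. Damage was left open too: cells without CXCL10 had a mitochondrial share higher by 0.753 points (-0.300 to 1.21), and the rule for this reading was tightened after the value had been seen. No biological explanation was tested, since the conditions are not mapped to hashtags.

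For the genes that differed between cycling and non-cycling cells, 1 of 100 swaps of the class labels within tumours (the real one) called as many genes, with 4768 in the real classes and 3243 as the highest other. The classes were called from the same cells' transcripts, so the swaps do not show that the difference goes beyond the scoring that made the classes.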

How the results depend on the processing

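Of 301 values under alternatives, 266 were the same, 2 weaker, 2 stronger and 31 moved, and 0 reversed; 14 of 32 results were the same under every alternative, and the cause of a move was not tested unless stated. The alternatives for comparisons of exposed with unexposed tumours were not run, since hashtags carry no condition. With the 60% hashtag rule the IFN-γ list spanned 3.38 and the type I list 1.97. With each tumour left out, spans were 3.48 to 3.58 (IFN-γ), 1.66 to 1.77 (MHC class I), 4.36 to 4.47 (MHC class II), 1.43 to 2.11 (type I) and 1.27 to 1.49 (TNF-NF-κB). No filter on cells gave 124 genes varying 4-fold. Chosen after seeing the data, other silhouette limits called 14 and 1 list pairs, and the 6 tumours in the lower part gave r = 0.729 for IFN-γ with TNF-NF-κB (exact p = 0.126). Under the stricter cell filter, which left 266 cells and favours cells of cluster 7, hypoxia had a median rho of -0.107 (exact p = 0.631) and TGF-β 0.301 (exact p = 0.00781). Under it GBP1 was seen in 38.2%, HLA-DRA in 14.9% and ICAM1 in 27.2% of cells. Without the clusters led by KRT81 and COL3A1 (chosen after seeing the data) the unfolded protein list had 0.0355 (exact p = 0.0449) and ICAM1 26.6%. Unthinned counts, which hold more UMIs per cell, gave 17.3% (CXCL10), 21.9% (IDO1), 45.8% (GBP1), 10.2% (CD274), 22.1% (HLA-DRA), 39.9% (ICAM1) and 14.9% (TNFAIP3). With doublets kept, values were 17.6% (CXCL10), 21.3% (IDO1), 38.4% (GBP1), 20.2% (HLA-DRA) and 27.8% (ICAM1). A limit of 40% mitochondrial UMIs (chosen after seeing the data) kept 3774 cells and gave 12.1% (CXCL10), 16.1% (IDO1), 31.3% (GBP1) and 7.12% (TNFAIP3). Without the tumour block 2289 genes were higher and 2221 lower in cycling cells, and no gene called in common had the opposite sign under any alternative.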

Other observations

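The custom feature Katushka, a far-red fluorescent protein that the labels do not mention, was seen in 2.00% of cells at equal depth, and its level per tumour ran from 0 in tumour 5 (3 counts would be 1.33 CPM) to 8.99 CPM (median 2.26), highest in tumour 6. In unthinned counts, which the cluster shares below use, Katushka was seen in 3.80% of cells. Its level was 11.4 CPM in cluster 3, led by IDO1 and CXCL10 (10.3% of cells), and 4.29 CPM in cluster 4 (6.98%). The cells of cluster 4 were deeper, with a median of 16518 UMIs against 10601 in all cells. Katushka's level was lower in the following clusters. It was 2.98 CPM in cluster 7 (5 UMIs) and 2.49 CPM in cluster 1 (2.41%). Cluster levels were pooled over tumours, and tumours 6, 7 and 8 gave 40, 87 and 119 of the 331 cells of cluster 3. So a difference between clusters can also come from tumour. Cluster 7 lacked CRIP1 (8.36 CPM against at least 248 CPM in every other cluster), encoding a LIM domain protein, and PLAT (4.78 against 187), encoding tissue plasminogen activator, and was depleted of IFI27 (248 against 2491), an interferon-inducible gene. These genes were chosen after their values had been seen.

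Whether the tumours fall into separate groups on the interferon lists was left open. For tumours 1 to 10 in order, the IFN-γ list stood at 4.35, 4.79, 5.85, 3.40, 3.18, 5.86, 6.76, 6.66, 3.48 and 3.26 mean log2 CPM, and the MHC class II list at 3.08, 3.60, 4.75, 2.54, 2.44, 5.33, 6.77, 6.80, 2.62 and 2.33. The best division into 2 parts had a silhouette of 0.692 for the IFN-γ list and 0.703 for MHC class II. The simulated limit was 0.7545, above the highest silhouette of any pathway list (0.7201), so these values do not show separate groups. The limit of 0.7 was chosen after these values had been seen. No tumour was assigned to a condition from them.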
